A study of Mus musculus with 6 samples.

How the data were processed

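RNA was measured in 6 libraries of endothelial cells sorted from mouse liver, 3 from mice on a control diet and 3 from mice on a diet with 1200 ppm PLX5622, each after 1 month. Per the labels' protocols, 1 liver lobe was dissociated, CD31-positive cells were collected by fluorescence-activated sorting, and non-stranded libraries were made from polyadenylated RNA. Groups and replicate numbers came from the sample titles, which call the samples biological replicates.

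The submitters' processing notes name STAR 2.7.10a, featureCounts, Subread 2.0.1, DESeq2 1.32.0, R 4.1.0 and the mouse build mm39. The annotation, the filters and the counting settings are not given in the sources used here. The authors' expression table holds 26264 genes in TPM, 1 column per library, each column scaled by the authors to the same total over the genes in the table. The authors' comparison table, made with DESeq2, holds 15097 genes with a mean normalized count, a log2 fold change and its standard error, a Wald statistic (a score, the fold change divided by its standard error), a p-value and an adjusted p-value. The adjusted p-value in the deposited table equals the Benjamini-Hochberg adjustment of its p-values over all of its genes, and its lowest mean normalized count is 5.38. The deposited log2 fold change is PLX5622 over control, as its sign against the TPM values showed. The authors' values are given as deposited and are kept apart from the values computed here. Gene symbols were used as the files give them. The mouse annotation at hand is of another build than the authors', so no coordinates are given.

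TPM hold no depth, so the number of reads per gene was worked out from the TPM values and the deposited mean normalized counts, for the 15097 genes in both tables. Under the recovered scale, 100% of values below 50 reads came out within 0.05 of a whole number in every library, and on simulated data for 14998 genes the same steps recovered 100% of values of 1 to 49 reads exactly. The recovered depth was between 14517956 and 32732209 reads per library. Floors and read numbers cover counting error only, since copies made by PCR are not independent molecules. A gene with 0 reads in the control libraries was set against a floor of 3 reads in each of them.

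The comparison was PLX5622 against control. Genes with a mean of at least 1 TPM over the 6 libraries were tested (13739 genes, leaving out 12525) on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Count models were not used as the main test because TPM are not counts. Intervals are 95% intervals of the limma fit. Before the data were examined, 34 gene lists were fixed for lipid and sterol metabolism, drug response, endothelial identity, cell state and the other cell types that the sort could hold. The lists were tested with limma's camera with a preset correlation between genes of 0.01, two-sided, adjusted over lists, and again with an estimated correlation. Of these, 33 could be tested: the mitochondrially encoded genes had 0 of 13 members in the table. Members were also adjusted over the list alone. The mean level of a list per library was compared by an exact two-sided permutation test, for which 0.1 is the smallest p with 3 libraries against 3. Lists share members: Csf1r belongs to the Kupffer and CSF1R lists, and Scd1 to the LXR and fatty acid lists.

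The genes named follow a rule set before the data were examined: the genes past the adjusted threshold without overlap between diets by size of fold change or, where fewer than 5 pass, those with the smallest p up to 5 per direction, leaving out predicted genes, pseudogenes and antigen receptor segments; per list the 2 members with the smallest p where none passes; and always a fixed set that includes Csf1r, Sqle, Insig1, Abca1, Pecam1, Stab2, Clec4f and Alb. Some genes that the rule names are not reported here. The genes that the authors' deposited table calls are named as well. Acat2, Lbr, Ebp, Cyp2c50, Slc40a1, H2-Aa and H2-Oa were named after their values were seen, to spell out small counts.

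The limma step was tested on simulated data for this comparison with 200 of 13739 genes changed: it called 21.6% of genes changed 1.5-fold, 43.6% of those changed 2-fold, 81.2% of those changed 4-fold and 92.4% of those changed 8-fold. On average 6.2 unchanged genes were called per draw. The simulated libraries varied independently of one another, so these shares may not hold for the real libraries. Alternatives were other pseudocounts, other filters on low values, quantile normalization, median-of-ratios scaling, limma without the trend, with robust fitting or with library weights, a block by replicate number, camera with an estimated correlation and leaving out each library in turn. voom on the recovered reads and a fit with a hepatocyte score as a covariate were added after the data were seen. The hepatocyte score is the mean log2(TPM + 1) over the hepatocyte list, centred on the mean of the 6 libraries. The median log2 fold change of all genes was -0.02, and the scalings moved it by at most 0.0183. Principal components were computed on the tested genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3 used to recover the reads.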

Results

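The data describe polyadenylated RNA of endothelial cells sorted from mouse liver. C57BL6 mice ate a control diet or a diet with 1200 ppm PLX5622 for 1 month. PLX5622 is an orally active inhibitor of the colony stimulating factor 1 receptor (CSF1R), a kinase on which most tissue macrophages depend. Cells that carried CD31 (PECAM1), a surface protein of endothelial cells, were sorted from 1 liver lobe, and each diet had 3 biological replicates, which gave 6 libraries. The question stated for the series was whether the drug affects cholesterol metabolism in endothelial cells outside the central nervous system. Read numbers recovered from the expression values came to 27738875, 32732209 and 14517956 reads for control replicates 1 to 3, and to 22157613, 16636664 and 20462315 reads for PLX5622 replicates 1 to 3. No replicates of a diet agreed within sampling noise, and the smallest chi-square per degree of freedom between libraries of one diet was 16.0. Pecam1, the gene for CD31, was detected in every library. It stood at 1682 ± 259 TPM (a length-scaled share of transcripts) on the control diet and at 1712 ± 148 TPM on PLX5622 (SD, n = 3 each). Without an unsorted sample these levels do not show how pure the sort was. In control replicate 1 the hepatocyte gene Alb, at 2368 TPM, stood above Pecam1, at 1981 TPM. In the other libraries Pecam1 stood above Alb. All fold changes below are of PLX5622 over control on the log2(TPM + 1) scale, which understates the change of weakly expressed genes, unless the authors' deposited table is named.

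The genes with the smallest p on the higher side were the small nucleolar RNAs Snora30 and Snord14d and 3 members of the X-linked Xlr family, Xlr3b, Xlr4a and Xlr4b. Xlr3b stood at 2.25 ± 1.80 TPM on the control diet and at 15.6 ± 3.42 TPM on PLX5622 (SD, n = 3 each), a log2 fold change of 2.52 (95% interval 1.46 to 3.57). Xlr4a had 1, 0 and 0 reads in the control libraries and 23, 48 and 23 reads in the PLX5622 libraries, and Xlr4b had 4, 0 and 0 against 22, 21 and 33. Members of this family are near-identical copies, so the assignment of reads among them is uncertain, as is that of reads in the small nucleolar RNAs, which lie within other genes and were counted here without strand. Snord14d had a log2 fold change of 0.84 (95% interval 0.52 to 1.17), and Snora30 of 2.50 (95% interval 1.55 to 3.45) from 0.321 ± 0.556 TPM on the control diet (SD, n = 3).

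On the lower side, the smallest p belonged to Ckap4, Lilrb4a, Spi1, Pld4 and Atp13a3. Spi1 encodes PU.1, the transcription factor of myeloid cells, and it stood at 3.61 ± 1.59 TPM on the control diet and at 0.274 ± 0.169 TPM on PLX5622 (SD, n = 3 each). Pld4, a nuclease of myeloid cells, stood at 3.65 ± 1.26 and 0.466 ± 0.190 TPM, and Lilrb4a, an inhibitory receptor of myeloid cells, at 4.43 ± 0.955 and 0.904 ± 0.271 TPM (SD, n = 3 each). The other members of this group were expressed at higher levels. Ckap4, a membrane protein of the endoplasmic reticulum, had 102 ± 8.11 TPM on the control diet against 69.0 ± 3.86 TPM on PLX5622 (SD, n = 3 each), and Atp13a3, a transport ATPase, 84.7 ± 18.2 against 46.7 ± 7.45 TPM. In each of these 10 genes the libraries of the diets did not overlap. No gene passed the test across all genes, however: limma called 0 of 13739 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.99998, while 459 genes had an unadjusted p under 0.05 (226 higher and 233 lower) where chance alone gives 687. The diets did not overlap in 8.68% of genes, where chance gives 10%. voom (limma) on the recovered reads also called 0 genes, with 459 at an unadjusted p under 0.05.

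The authors' deposited table, made with DESeq2, calls 11 genes at an adjusted p under 0.05, 7 of them higher and 4 lower on PLX5622, with 480 genes of 15097 at an unadjusted p under 0.05. The higher ones in the authors' deposited table are Cyp2b10, a drug-metabolizing cytochrome P450, with a log2 fold change of 8.63 (SE 1.38, adjusted p = 5.60e-06), the imprinted noncoding RNA H19 with 1.79 (SE 0.316, adjusted p = 9.87e-05), Xlr3b with 2.74, Cyp2c54 with 3.28, Xlr4a with 6.78, Dmbt1 with 11.13 and the organic anion transporter Slco2b1 with 0.69. The lower ones in the authors' deposited table are Spi1 with -3.70 (SE 0.807, adjusted p = 0.00839), Pld4 with -2.95, Atp13a3 with -0.84 and Ckap4 with -0.55. In the limma fit to the TPM values all 11 had the same sign, an unadjusted p under 0.05 and no overlap between the diets, but none passed the adjusted threshold. H19 stood at 29.0 ± 5.47 TPM on the control diet and at 99.7 ± 48.7 TPM on PLX5622 (SD, n = 3 each), and Slco2b1 at 25.6 ± 0.587 and 40.9 ± 6.17 TPM. Dmbt1, a secreted scavenger receptor protein, rested on single libraries: PLX5622 replicates 2 and 3 had 13.2 and 33.3 TPM, PLX5622 replicate 1 had 0.0613 TPM, and the control libraries held 1, 0 and 0 reads. Across 13470 genes in both tables the fold changes had a Pearson correlation of 0.919. Genes are not independent replicates, and both sets of fold changes come from the same libraries.

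**Figure D1:**
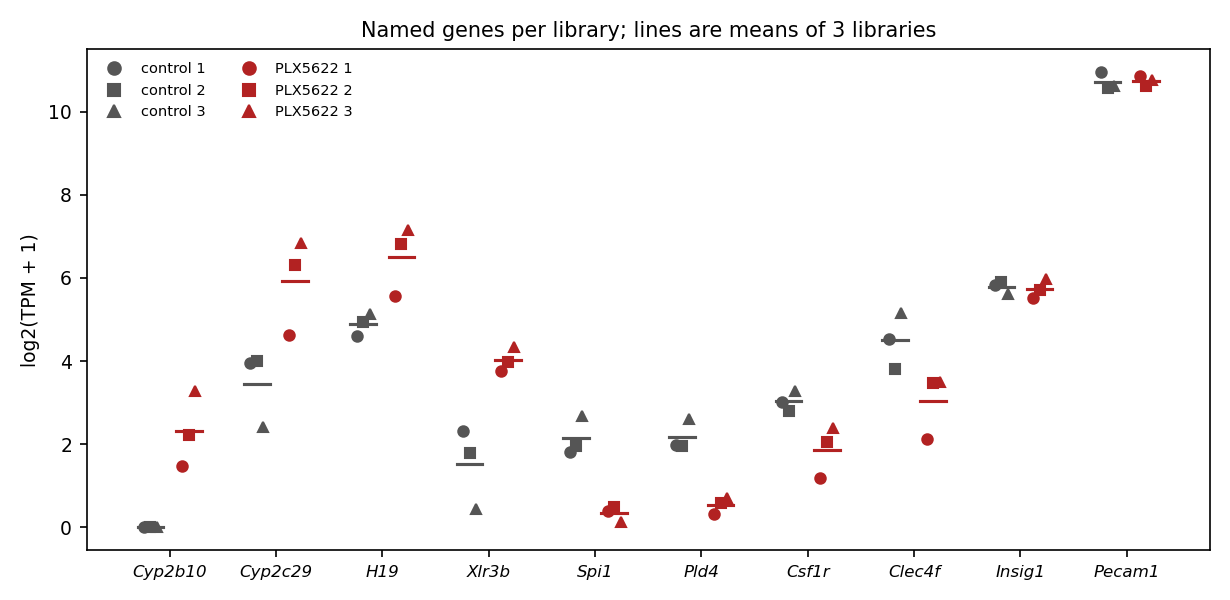
Level of 10 named genes in each library, as log2(TPM + 1), with control libraries in grey, PLX5622 libraries in red and the mean of the 3 libraries of each diet as a line. Cyp2b10 is at 0 in the 3 control libraries, Spi1 and Pld4 are lower in every PLX5622 library than in every control library, and Insig1 and Pecam1 overlap between the diets.

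The genes of cholesterol biosynthesis bear on the stated question, and no single member passed an adjusted threshold. The members with the smallest p were Hmgcs1, an early enzyme of the pathway, which stood at 28.0 ± 7.47 TPM on the control diet and at 20.8 ± 0.915 TPM on PLX5622 (SD, n = 3 each), a log2 fold change of -0.39 (95% interval -0.82 to 0.05), and Sc5d, a late enzyme of the pathway, at -0.43 (95% interval -0.94 to 0.08). Sqle, the enzyme of the first oxygen-dependent step, was at -0.39 (95% interval -0.99 to 0.22). Of 20 tested genes in the list, 17 had a fold change below 0 and 3 above it (Acat2, Lbr and Ebp, at 0.08, 0.03 and 0.02). With limma, 0 of the 20 passed adjusted over all genes, 0 passed adjusted over the list alone, and 0 had an unadjusted p under 0.05; 2 did not overlap between diets, where chance gives 2. Of 21 members in the authors' deposited table, 0 pass, also when adjusted over the list alone, and Hmgcs1 and Sc5d have unadjusted p-values of 0.0479 and 0.0493.

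As a group the cholesterol biosynthesis genes had a mean log2 fold change of -0.14, with an adjusted p of 0.0685 by limma's camera with a preset correlation and an adjusted p = 0.886 with an estimated correlation. The mean level of the list in the 6 libraries gave an exact two-sided permutation p of 0.4, where 0.1 is the smallest that 3 libraries against 3 allow. The control libraries spread over 4.31, 4.07 and 3.80 in that mean level, and the PLX5622 libraries, at 3.90, 3.94 and 3.92, lay within that range. The value depended on single libraries: without control replicate 1 it was -0.01, and without control replicate 3 it was -0.27 with a camera adjusted p of 9.05e-06 (limma), in a range of 9.05e-06 to 0.978 over all alternatives. Without PLX5622 replicate 2 it was -0.15 with an adjusted p of 0.0357 (limma camera), and with library weights it was -0.06. voom (limma) on the recovered reads gave -0.19 and an adjusted p of 0.00859.

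**Figure D2:**
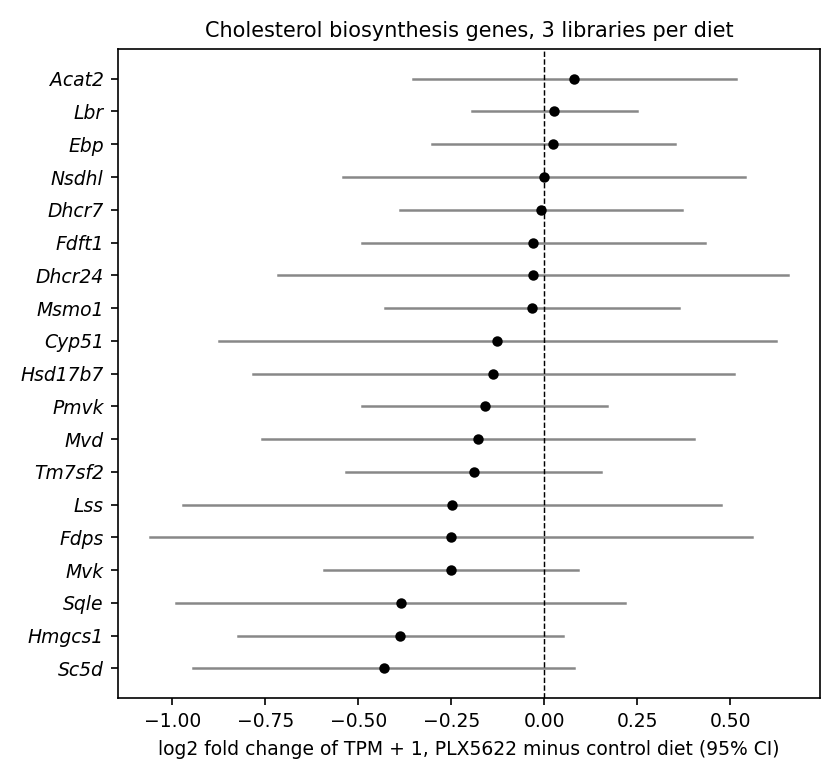
Log2 fold change (dots) and 95% confidence interval (lines) of 19 of the 20 tested cholesterol biosynthesis genes, PLX5622 minus control diet, from 3 libraries per diet. Each interval drawn includes 0, and 16 of the 19 dots lie below 0.

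Genes that sense and take up sterols did not differ detectably as a group. Insig1, which retains the sterol sensor in the endoplasmic reticulum, stood at 53.9 ± 5.48 TPM on the control diet and at 52.6 ± 8.42 TPM on PLX5622 (SD, n = 3 each), a log2 fold change of -0.04 (95% interval -0.37 to 0.29). Lrp1, a lipoprotein receptor, was at -0.45 (95% interval -0.99 to 0.09). It was the 1 gene of the list without overlap between diets, where chance gives 1.70. The list of 17 tested genes had a mean of -0.10, with 13 members below 0 and a limma camera adjusted p of 0.310. Targets of the oxysterol receptor LXR and genes of cholesterol efflux were evenly divided, 10 above and 10 below 0, with a mean of -0.08 and a limma camera adjusted p of 0.890. Without single libraries the sterol sensing mean was between -0.14 and -0.06 and the LXR mean between -0.12 and -0.02, and neither list had a call. The efflux transporter Abca1 was at 0.23 (95% interval -0.13 to 0.59) and its relative Abca7 at -0.23 (95% interval -0.51 to 0.06). In these lists limma passed 0 genes adjusted over all genes and 0 adjusted over the list alone. With limma, 0 of the sterol sensing genes and 1 of the LXR targets, Scd1, had an unadjusted p under 0.05. In the authors' deposited table, 0 members of either list pass, also when adjusted over the list alone. At an unadjusted p under 0.05 it has 2 of 19 sterol sensing genes lower and 0 higher, with Lrp1 at 0.00913 (DESeq2).

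Genes of fatty acid synthesis and desaturation were lower as a group on PLX5622. Their mean log2 fold change was -0.38 over 21 genes, 18 of them below 0, with a limma camera adjusted p of 2.05e-04 and an adjusted p = 0.886 with an estimated correlation. The exact two-sided permutation p of the list level was 0.3. Scd1, the desaturase that makes monounsaturated fatty acids, stood at 298 ± 211 TPM on the control diet and at 86.9 ± 49.7 TPM on PLX5622 (SD, n = 3 each), a log2 fold change of -1.70 (95% interval -3.01 to -0.40). Thrsp, a nuclear protein of lipogenic tissues, was at -0.99 (95% interval -1.81 to -0.18). These were the 2 members with an unadjusted p under 0.05; limma passed 0 adjusted over all genes and 0 adjusted over the list alone. Of 21 members in the authors' deposited table, 0 pass adjusted over all genes and 1, Thrsp, passes adjusted over the list alone. The call rested on control replicate 1, in which the list level was 5.32 against 4.79 and 4.57 in the other control libraries: without it the mean was -0.16 and the camera adjusted p 0.357 (limma), in a range of 2.13e-08 to 0.886 over all alternatives. The same library had the highest level of hepatocyte markers, with a centred hepatocyte score of 0.853 on the log2 scale. Genes of fatty acid oxidation and targets of the nuclear receptor PPAR had a mean of 0.07 (limma camera adjusted p = 0.144), with Angptl4, a secreted inhibitor of lipoprotein lipase, at 0.75 (95% interval 0.24 to 1.25) and the fatty acid binding protein gene Fabp4 at 0.33 (95% interval -0.07 to 0.74). Without single libraries that mean was between -0.00204 and 0.17. It passed without PLX5622 replicate 1, at an adjusted p of 0.0151 (limma camera), in a range of 0.0151 to 0.886 over all alternatives.

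Genes that the xenobiotic receptors PXR and CAR induce were higher as a group on PLX5622. Cyp2b10, a classical CAR target, had 0 reads in each of the 3 control libraries and 26, 41 and 118 reads in PLX5622 replicates 1 to 3, which was at least 22.8-fold higher against a floor of 3 reads per control library. Cyp2c29, another cytochrome P450, stood at 11.3 ± 6.01 TPM on the control diet and at 71.7 ± 45.0 TPM on PLX5622 (SD, n = 3 each), a log2 fold change of 2.47 (95% interval 1.02 to 3.92). Cyp2c54 was at 2.09 (95% interval 0.65 to 3.52), and Cyp2c50 at 2.00 (95% interval 0.38 to 3.62). These P450 genes belong to families with closely similar members, so some reads could have been assigned to a neighbouring copy. The mean of the list was 0.62 over 23 genes, 16 of them above 0, with a limma camera adjusted p of 7.48e-05 and an adjusted p = 0.749 with an estimated correlation. The 4 genes named here were those with an unadjusted p under 0.05; limma passed 0 adjusted over all genes and 1, Cyp2b10, adjusted over the list alone. In the authors' deposited table, 3 of 27 members, Cyp2b10, Cyp2c29 and Cyp2c54, pass adjusted over the list alone. The list level of PLX5622 replicate 1, 3.04, lay below that of control replicate 1, 3.45, and the exact two-sided permutation p over the libraries was 0.2. The mean was 0.37 with a pseudocount of 5 TPM and 1.03 with voom (limma) on the recovered reads. Hepatocyte markers, which mark the cells where these P450 genes are most active, had a mean log2 fold change of -0.32. Targets of the receptors AhR and NRF2 had a mean of 0.10 (limma camera adjusted p = 0.649), with Cyp1b1 at 0.26 and Nqo1 at 0.15. Without single libraries that mean was between -0.01 and 0.28. It passed without control replicate 1, at an adjusted p of 0.0247 (limma camera), in a range of 0.0247 to 0.918 over all alternatives.

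Markers of Kupffer cells, the resident macrophages of the liver sinusoid, were lower as a group on PLX5622. Of 19 tested genes 18 had a fold change below 0, with a mean of -0.67 (limma camera adjusted p = 6.80e-10). The adjusted p = 0.749 with an estimated correlation, which ended the call. Clec4f, a lectin of Kupffer cells, stood at 23.2 ± 10.8 TPM on the control diet and at 7.91 ± 3.93 TPM on PLX5622 (SD, n = 3 each), a log2 fold change of -1.47 (95% interval -2.52 to -0.42). Csf1r, the gene of the drug's target, stood at 7.27 ± 1.35 and 2.87 ± 1.49 TPM (SD, n = 3 each), a log2 fold change of -1.17 (95% interval -1.95 to -0.38). The complement gene C1qa was at -1.02 (95% interval -1.67 to -0.38). The exception was the iron exporter Slc40a1 at 0.09, which stood at 71.7 ± 36.0 TPM on the control diet and at 72.2 ± 27.4 TPM on PLX5622 (SD, n = 3 each). Each PLX5622 library lay below each control library in the mean level of the list, at 2.20, 2.91 and 2.71 against 3.30, 3.00 and 3.54, with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. In 7 genes the libraries did not overlap between diets, where chance gives 1.90, and 7 had an unadjusted p under 0.05; limma passed 0 adjusted over all genes and 0 adjusted over the list alone. Genes of this list vary together, at an estimated correlation of 0.335, so the 7 are not independent of one another. Of 20 members in the authors' deposited table, 0 pass adjusted over all genes and 6 pass adjusted over the list alone. The mean was -0.88 with a pseudocount of 0.1 TPM and -0.41 with 5 TPM.

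**Figure D3:**
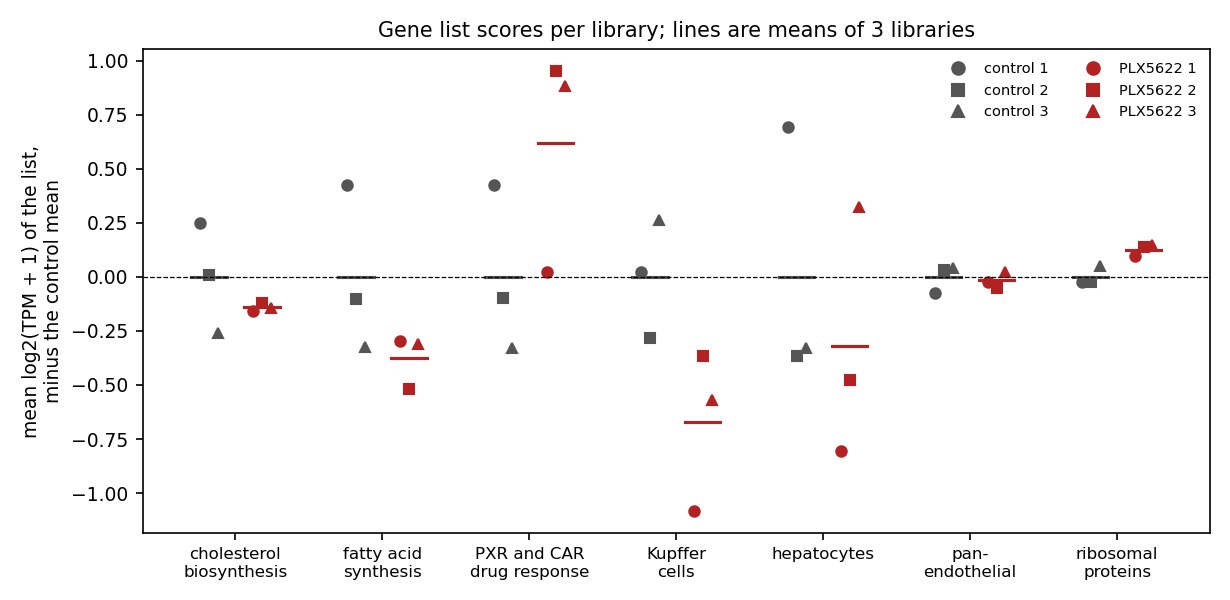
Mean log2(TPM + 1) of 7 gene lists in each library, minus the mean of the control libraries, with control libraries in grey, PLX5622 libraries in red and the mean of the 3 libraries of each diet as a line. The PLX5622 libraries lie below the control libraries for Kupffer cell markers and above them for ribosomal protein genes, and the diets overlap in the other 5 lists.

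The list of CSF1R axis genes and related kinases, which includes Csf1r, had a mean of -0.07 over 10 tested genes, 6 of them below 0 (limma camera adjusted p = 0.709, in a range of 0.0667 to 0.989 over all alternatives). The mean was between -0.16 and -0.00279 without single libraries, -0.33 with a filter at a mean of 5 TPM and 0.01 with voom (limma) on the recovered reads. In the authors' deposited table, 2 of 11 members, Csf1r and Csf3r, pass adjusted over the list alone. Csf1, the ligand of the receptor, stood at 107 ± 17.2 TPM on the control diet and at 87.8 ± 1.40 TPM on PLX5622 (SD, n = 3 each), a log2 fold change of -0.28 (95% interval -0.56 to 0.01), and the granulocyte receptor gene Csf3r was at 0.76 (95% interval 0.10 to 1.43). Among markers of monocytes and dendritic cells the lysozyme gene Lyz2, which macrophages also express, was at -1.70 (95% interval -2.81 to -0.60) and was the 1 gene that passed adjusted over the list alone, in limma and in the authors' deposited table, while S100a4 was at 0.67 (95% interval -0.31 to 1.65). That list had a mean of -0.11 and a median of 0.09 over 6 genes (limma camera adjusted p = 0.817). Genes of antigen presentation on major histocompatibility complex (MHC) class II were lower as a group, with a mean of -0.43 over 7 genes (limma camera adjusted p = 0.00451, and adjusted p = 0.749 with an estimated correlation). The exact two-sided permutation p of the list level was 0.3. H2-Eb1 stood at 21.8 ± 8.70 TPM on the control diet and at 10.4 ± 1.40 TPM on PLX5622 (SD, n = 3 each), and the invariant chain gene Cd74 at 73.0 ± 21.4 and 41.2 ± 11.6 TPM. With H2-Aa, at a log2 fold change of -0.63, these were the 3 genes that passed in limma adjusted over the list alone, and 0 passed adjusted over all genes. In the authors' deposited table the same 3 and H2-Oa pass adjusted over the list alone. The group call was lost without control replicate 1, at a mean of -0.25 and an adjusted p of 0.204 (limma camera), without PLX5622 replicate 1, at -0.25 and 0.207, and with library weights, at -0.31 and 0.0630, in a range of 5.08e-06 to 0.749 over all alternatives.

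Endothelial identity genes did not differ detectably between the diets. The 20 genes common to endothelial cells had a mean log2 fold change of -0.02 (limma camera adjusted p = 0.999), with 9 above and 11 below 0 and limits of the 95% intervals between -0.70 and 0.61. Ramp2, a receptor component of vascular endothelium, stood at 1223 ± 40.4 and 1112 ± 96.7 TPM, and the secreted endothelial factor gene Egfl7 at 1754 ± 69.2 and 1921 ± 144 TPM on control and PLX5622 diets (SD, n = 3 each). Markers of liver sinusoidal endothelium had a mean of -0.11 (limma camera adjusted p = 0.649). The sinusoidal scavenger receptor gene Stab2 varied widely within each diet, at 781 ± 379 and 479 ± 202 TPM (SD, n = 3 each). The Fc receptor gene Fcgr2b, at 0.40 (95% interval 0.08 to 0.72), was the 1 sinusoidal marker with an unadjusted p under 0.05, and Gpr182 was at -0.21 (95% interval -0.55 to 0.13). Without control replicate 1, which had 343 TPM of Stab2, the sinusoidal list was at -0.33 with an adjusted p of 2.58e-06 (limma camera), and with library weights at -0.23 and 0.0160, in a range of adjusted p of 2.58e-06 to 0.924 over all alternatives. With 1 library left out, the mean log2 fold change of the sinusoidal list reached up to 0.0189.

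Genes of the central sinusoid and central vein had a mean of 0.01 (limma camera adjusted p = 0.483), and those of portal and arterial endothelium a mean of 0.10 (limma camera adjusted p = 0.144), with the Notch target Hey1 at 0.64 (95% interval 0.10 to 1.18) and the arterial kinase gene Bmx at 0.44 (95% interval 0.03 to 0.85). The portal and arterial list passed with the hepatocyte score as a covariate, at 0.12 and an adjusted p of 0.0452 (limma camera), in a range of 0.0452 to 0.749 over all alternatives. Rab3b, in the central list, was at -0.96 (95% interval -2.03 to 0.12). Without single libraries the mean of the central list was between -0.08 and 0.15. It passed without PLX5622 replicate 2, at an adjusted p of 0.00859 (limma camera), in a range of 0.00859 to 0.886 over all alternatives. Genes by which endothelium acts on its neighbours, including the Kupffer cell niche, had a mean of 0.03 (limma camera adjusted p = 0.709). Id1, in this list, was at 0.28 (95% interval 0.05 to 0.51). Genes of endothelial activation and adhesion had a mean of 0.04 (limma camera adjusted p = 0.709), with Icam2 at -0.20 (95% interval -0.41 to 0.01). Without single libraries that mean was between -0.15 and 0.23. It passed at 0.23 without control replicate 1, at an adjusted p of 0.00299 (limma camera), and without PLX5622 replicate 3, at 6.75e-04, in a range of 6.75e-04 to 0.924 over all alternatives. Markers of lymphatic endothelium were higher as a group, with a mean of 0.33 over 7 genes (limma camera adjusted p = 0.00586, and adjusted p = 0.749 with an estimated correlation). The exact two-sided permutation p of the list level was 0.3. Prox1, the transcription factor of lymphatic identity, was at 0.38 (95% interval -0.02 to 0.79) and Fgl2 at 0.66 (95% interval 0.13 to 1.19). The group call was lost without control replicate 1, at 0.22 and an adjusted p of 0.254 (limma camera), and without PLX5622 replicate 2, at 0.19 and 0.130, in a range of 1.68e-04 to 0.749 over all alternatives. In these 5 lists limma passed 0 genes adjusted over all genes and 0 adjusted over the list alone. In the authors' deposited table, 1 of their members, Fgl2, passes adjusted over the list alone.

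RNA of hepatocytes was present in every library and varied between libraries of the same diet. Alb, the gene for serum albumin, stood at 2368, 1135 and 929 TPM in control replicates 1 to 3 and at 552, 442 and 978 TPM in PLX5622 replicates 1 to 3, a log2 fold change of -1.13 (95% interval -2.05 to -0.21). Trf, which encodes transferrin, was at -0.69 (95% interval -1.44 to 0.06). The hepatocyte list had a mean of -0.32 over 22 genes, 18 below 0 (limma camera adjusted p = 0.00586, and adjusted p = 0.886 with an estimated correlation), and the exact two-sided permutation p over the libraries was 0.5. The direction depended on control replicate 1, without which the mean was 0.03, and the call was lost without PLX5622 replicate 1, at -0.08 and an adjusted p of 0.870 (limma camera), and with library weights, at -0.11 and 0.489, in a range of 4.03e-09 to 0.925 over all alternatives. Markers of stellate cells and fibroblasts had a mean of 0.05 (limma camera adjusted p = 0.649), with Dcn at 0.37 and Lrat at 0.54. Without single libraries that mean was between -0.08 and 0.22. It passed without control replicate 2, at an adjusted p of 0.0302 (limma camera), in a range of 0.0302 to 0.978 over all alternatives. Cholangiocyte markers spread widely, with Krt19 at 2.49 ± 2.89 TPM on the control diet and at 6.05 ± 5.17 TPM on PLX5622 (SD, n = 3 each), and a list mean of -0.04 (limma camera adjusted p = 0.817). Without PLX5622 replicate 1 the cholangiocyte mean was 0.67, at an adjusted p of 0.0208 (limma camera), in a range of 0.0208 to 0.994 over all alternatives.

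Genes for ribosomal proteins were slightly and uniformly higher on PLX5622. All 32 tested genes had a fold change above 0, with a mean of 0.13 (limma camera adjusted p = 3.75e-10, and adjusted p = 0.749 with an estimated correlation). Rpl11 stood at 501 ± 27.4 TPM on the control diet and at 582 ± 23.9 TPM on PLX5622, and Rpl37 at 392 ± 25.9 and 453 ± 16.7 TPM (SD, n = 3 each). The libraries did not overlap in 17 genes, where chance gives 3.20, and the exact two-sided permutation p of the list level was 0.1, the smallest possible; limma passed 0 genes adjusted over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05. Genes of this list vary together, at an estimated correlation of 0.187, so the 17 are not independent of one another. The direction held under quantile and median-of-ratios scaling. Immediate early and heat shock genes had a mean of 0.09 over 27 genes (limma camera adjusted p = 0.0117, and adjusted p = 0.886 with an estimated correlation), with Fos at 5296 ± 436 TPM on the control diet and at 6615 ± 621 TPM on PLX5622 (SD, n = 3 each). Genes of the unfolded protein response had a mean of -0.10 over 21 genes (limma camera adjusted p = 0.0480, and adjusted p = 0.886 with an estimated correlation), with Chac1 at -0.35 (95% interval -0.78 to 0.08) and Pdia6 at -0.22 (95% interval -0.53 to 0.09). The exact two-sided permutation p of the list level was 0.6 for the immediate early list and 0.4 for the unfolded protein response. Both stress gene calls depended on the processing and on single libraries. That of the immediate early list was lost under quantile normalization, at 0.06 and an adjusted p of 0.219 (limma camera), with no filter on low values, with the hepatocyte score as a covariate, and without control replicate 3 or PLX5622 replicates 1 or 2, down to 0.00267, in a range of 2.99e-08 to 0.886 over all alternatives. That of the unfolded protein response was lost under quantile and median-of-ratios scaling, without the intensity trend, with no filter on low values, with the hepatocyte score as a covariate, and with library weights, at -0.05 and 0.489 (limma camera). It was also lost without control replicate 1, at -0.0148, or any 1 of the PLX5622 libraries, in a range of 0.00134 to 0.978 over all alternatives.

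Other divisions of the same libraries gave as many list calls as the diets. The first principal component held 29.2% of the variance, and the diets overlapped on it. The second held 21.3%, and every PLX5622 library lay above every control library on it, narrowly: the lowest PLX5622 value was 0.507 and the highest control value 0.157, on an axis that reached from -35.7 in control replicate 3 to 28.8 in PLX5622 replicate 2. In all, 9 of 33 tested lists passed limma's camera with the preset correlation (Kupffer cells, MHC class II, fatty acid synthesis, hepatocytes and the unfolded protein response below 0, and PXR and CAR targets, lymphatic endothelium, ribosomal proteins and immediate early genes above 0), and 0 of 33 passed with an estimated correlation. Among the 10 ways to divide the 6 libraries into groups of 3, the others gave between 5 and 16 lists by the same preset test.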

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

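The voom fit on recovered reads and the fit with a hepatocyte score as covariate were chosen after the data were seen; the other alternatives were planned. limma called 0 genes higher and 0 lower under every alternative run, and 0 at an adjusted p under 0.1 in the fit as designed, with 304 to 847 genes at an unadjusted p under 0.05 among the fits on the same 13739 genes and a smallest adjusted p of 0.0506, without control replicate 3. Counts with edgeR or DESeq2, planned in case the authors gave read counts, were not run. The authors' deposited table calls 8 genes higher and 5 lower at an adjusted p under 0.1. With an estimated correlation the number of lists past the threshold was 0 instead of 9, and the Kupffer list, at -0.67, no longer passed. Its estimated correlation was 0.335, above the preset 0.01. Shared variation of the genes of a list cannot be the only reason for lost calls. The unadjusted p (limma camera) also rose for neutrophils, from 0.0159 to 0.0716, at an estimated correlation of -0.247. What else contributed was not tested. The other alternatives gave 7 to 12 lists. The cholesterol biosynthesis list stayed below 0, over a leave-one-out range of -0.27 to -0.0145. It passed the threshold without control replicate 3 or PLX5622 replicate 2. These had the lowest control level of the list, 3.80, and the highest PLX5622 level, 3.94, so leaving out either widens the difference. It also passed with voom on recovered reads (-0.19), and the cause of that was not tested. Leaving out single libraries changed the sign of 17 lists at least once, and 11 of these had a call with all libraries or without 1 of them. In 7 of the 11 the call had the sign seen with all libraries. In the other 4, the fit with all libraries or the fit of the other sign had a call: hepatocytes ranged from -0.64 to 0.0278 (without control replicate 1), the cell cycle from -0.57 to 0.24 (without control replicate 2), cholangiocytes from -0.51 to 0.67 (without PLX5622 replicate 1) and the interferon response from -0.22 to 0.0762 (without PLX5622 replicate 3); the cause was not tested. Over all lists, 625 alternatives gave 33 lost, 32 gained and 5 reversed calls, of which that of the hepatocyte list with its own score as a covariate is at 0 by construction. Over 83 named genes, 0 of 1478 alternatives passed the threshold and 24, in 7 genes, had another sign. With the replicate number as a block, limma called 0 genes higher and 0 lower, with 821 at an unadjusted p under 0.05, and the interferon response list gained a call at -0.09. Deviations of same-numbered libraries correlated at 0.196, 0.136 and 0.0873, and every library correlated best with its own number, a hint from the data, not from the labels. The deviations were taken from the mean of each diet, so these correlations depend on one another and the hint is weak. Control replicate 3 was the shallowest library, at 14517956 reads, and PLX5622 replicate 2 was next, at 16636664 reads. Whether depth affected any call was not tested.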

Other observations

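The tests on Kupffer cell markers, the test of more hepatocyte RNA behind the P450 transcripts and the use of a hepatocyte score as a covariate were chosen after the data were seen; the other tests were set before their results.

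Gene groups not described so far had no call in the fit as designed, but camera's adjusted p (limma) ranged over the alternatives from 7.77e-06 to 0.886 for the interferon list, from 1.97e-06 to 0.886 for the cell cycle list and from 0.0373 to 0.980 for the hypoxia list. Interferon response genes had a mean log2 fold change of -0.09 over 30 genes, with Psmb8 at -0.19 (limma camera adjusted p = 0.114). Cell cycle genes had a mean of -0.21 over 30 genes, with E2f1 at -0.61 and Rrm1 at -0.27 (limma camera adjusted p = 0.0728), and their level in control replicate 2, 4.26, stood above the 2.63 to 3.26 of the other 5 libraries. Hypoxia and glycolysis genes had a mean of 0.03 (limma camera adjusted p = 0.709), with Bnip3, a mitophagy receptor gene, at 0.33 and the vasodilator gene Adm at -0.30. The extracellular matrix list had a mean of 0.01 over 21 genes (limma camera adjusted p = 0.709), 9 above and 12 below 0. At an unadjusted p under 0.05, 1 member was higher and 3 were lower, and 3 did not overlap between diets, where chance gives 2.10. The 2 members with the smallest p were chains of basement membrane collagen. Col4a1 stood at 647 ± 109 TPM on the control diet and at 479 ± 13.7 TPM on PLX5622, and Col4a2 at 371 ± 68.0 and 278 ± 1.29 TPM (SD, n = 3 each), without overlap between the diets. With limma, 0 members passed adjusted over all genes and 0 adjusted over the list alone.

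Few blood cell markers passed the filter on low values: 3 of 11 for neutrophils, 2 of 19 for T and NK cells, 5 of 14 for B and plasma cells and 2 of 10 for erythroid cells. Neutrophil markers had a mean of 0.37 (limma camera adjusted p = 0.0525, in a range of 0.00756 to 0.749 over the alternatives), with Lcn2 at 0.29, and 1 of 3 members in the authors' deposited table, Csf3r, passes adjusted over the list alone. T and NK cell markers had a mean of -0.15 over 2 genes, Lck at -0.16 and Il2rb at -0.14 (limma camera adjusted p = 0.709). B and plasma cell markers had a mean of -0.14 over 5 genes, with Blk at -0.55 and Ebf1 at 0.35 (limma camera adjusted p = 0.709). Platelet markers had a mean of 0.14 over 7 genes (limma camera adjusted p = 0.704), where Gp9, at 1.70 ± 0.537 TPM on the control diet and 4.75 ± 1.37 TPM on PLX5622 (SD, n = 3 each), was the 1 gene that passed in limma adjusted over the list alone and Pf4 was at -0.24. Erythroid markers had a mean of 0.11 over 2 genes, Alas2 at 0.16 and Epor at 0.07 (limma camera adjusted p = 0.709). These means moved with single libraries left out: between -0.12 and 0.42 for platelets and between -0.29 and 0.45 for erythroid cells. The ranges were -0.40 to -0.00877 for T and NK cells, -0.33 to -0.00113 for B and plasma cells and 0.22 to 0.64 for neutrophils.

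Kupffer cell markers were lower on PLX5622, by a mean log2 fold change of -0.67 (SE over genes 0.10). Less carry-over of other cells in step with hepatocyte RNA stays open, since the hepatocyte list and its single genes differ. Without control replicate 1 the hepatocyte mean was 0.03, while the Kupffer mean stayed between -0.83 and -0.47 without single libraries. With the hepatocyte score as a covariate the Kupffer mean was -0.62 (SE over genes 0.0887). That SE measures no spread between libraries, and the covariate left the hepatocyte gene Alb at -0.81, so this fit decides little by itself. A smaller share of all other cell types stays open: the stellate list lay above the Kupffer list by 0.72 (SE over genes 0.133), but its own mean was between -0.08 and 0.22 without single libraries, and the difference between their levels did not separate the diets in every library, so these cannot be told apart. Fewer macrophages in the CD31 sort on the diet stays open as well: that 94.7% of the tested markers were lower restates the pattern and decides nothing. Lower expression of the same genes within macrophages was not tested.

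Drug-response P450 transcripts were higher on PLX5622. More hepatocyte RNA in those libraries is argued against by the hepatocyte list, whose mean was -0.32 (SE over genes 0.0657), while Cyp2b10, Cyp2c29, Cyp2c54 and Cyp2c50 were higher by 2.00 to 2.47. The hepatocyte mean was between -0.64 and 0.03 without single libraries, which is still below the smallest of these rises. Whether the transcripts came from carried-over hepatocytes with an induced drug response or from the endothelial cells cannot be told apart: the hepatocyte score of PLX5622 replicates 1 to 3, at -0.644, -0.319 and 0.485, has the same order as Cyp2b10, at 1.78, 3.63 and 8.76 TPM, but 3 libraries allow no exact one-sided permutation p below 0.167. Cyp2c29, at 23.7, 78.2 and 113 TPM, has that order as well, while Cyp2c54, at 1.88, 15.9 and 11.8 TPM, does not. Either source may contribute.

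Fatty acid synthesis genes were lower on PLX5622, by a mean of -0.38 (SE over genes 0.0941). Less hepatocyte RNA as the whole cause stays open. With the hepatocyte score as a covariate the mean was -0.27 (SE over genes 0.0848), but this SE measures no spread between libraries. The same covariate left the hepatocyte gene Alb at -0.81, from -1.13 without it, so the covariate cannot decide the question. A single control library is consistent with the data, since without control replicate 1 the mean was -0.16 (SE over genes 0.0681) and the camera call was lost. An effect of the diet itself stays open and was not tested apart from that library.

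Other divisions of the 6 libraries bear on all of these. With 10 splits no share can fall under 0.05, and 7 of them gave as many genes at an unadjusted p under 0.05 as the 459 of the real split, with 1485 as the highest of the others. All 10 gave 0 genes at the adjusted threshold by limma, and 8 gave as many lists as the 9 of the real split, with 16 as the highest of the others. The 4 splits that put control replicate 1 and PLX5622 replicate 1 on the same side gave 819, 947, 1143 and 1485 genes, more than any other split, where 562 was the highest. This points to a structure of the libraries other than diet. Both of these libraries carry replicate number 1, and the labels do not say what that number means. They also had the lowest Stab2, at 343 and 279 TPM, against 474 to 1007 TPM in the other libraries. The cause was not tested.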
